A study of Mus musculus with 15 samples.

How the data were processed

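RNA-seq was carried out on mouse embryonic fibroblasts (MEF) of the ICR strain. The 15 libraries fell by their titles into 3 groups of 5, called MEF, MGT and MΔGΔT. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into directional libraries, and transduced cells were collected 1 week after they received retrovirus. The labels do not say whether the MEF group received an empty virus, or whether the 5 replicates of a group were separate cultures, so the spread between replicates may hold less than the spread between cultures.

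The deposited table lists 14091 features by gene symbol, with 4 values per feature and library. Per the file headers the first is an expression value, and these values were whole-number counts. The second is headed as normalized, per the file headers, and this deposited signal was the count multiplied by 1 constant per library, to the rounding of the printed values. The deposited transformed values differed from the log2 of the normalized value plus 1 by at most 0.005. The deposited RPKM values (reads per kilobase and mega-read) also carry, by their definition, a factor for the length of each gene. Apart from it, 1 factor per library related them to the counts, within a tolerance of 1.2%. This held for at least 82.6% of well-counted genes in each library. The genome build was mm10, per the submitters' processing notes. The read mapper, the counting tool and whether counting used strand are not given in the sources used here. Reads of overlapping or antisense genes, and reads shared by near-identical genes, can therefore not be assigned with certainty. Every listed feature had a count above 0 in at least 3 libraries. A date stood in place of the symbol for 21 features holding 0.26% of the counts, which were kept for library sizes and tests but not named. Of the symbols, 13744 (97.5%) matched the GENCODE M21 annotation, from which identifiers, coordinates, gene length and GC content were taken.

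The counts were analysed with edgeR 4.0.16 in R 4.3.3. Features with low counts were removed with filterByExpr by group, which left 13328, and library sizes were adjusted for composition by TMM. A quasi-likelihood model with robust settings was fitted to all 15 libraries together, with group as the only term and 12 residual degrees of freedom. The biological coefficient of variation was 4.86%. Each of the 3 pairs of groups was compared by the quasi-likelihood F-test, and p was adjusted by the Benjamini-Hochberg method over all tested genes of the comparison. Genes with an adjusted p under 0.05 are called higher or lower, and the words rose and fell are used for these genes alone. Every adjusted p of a gene is from this test unless another is named. The SE of a log2 fold change is the one implied by the F statistic. Levels are counts per mega-count (CPM) of the TMM-adjusted library size, as mean ± SD. For a gene with 0 counts in all 5 libraries of a group, the fold is a lower bound computed against a floor of 3 counts over the group. For a gene with 1 to 3 counts in a group, the ratio is given with its 95% counting interval, which covers counting error only.

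The tests, the alternatives, 31 gene lists and the rule for naming genes were fixed before the data were examined. The rule names Mef2c, Gata4 and Tbx5, a fixed panel of marker genes, and per comparison the 6 largest rises and 6 largest falls. These largest changes were taken among called genes with a mean log2 CPM above 1, without overlap between the 5 and 5 libraries, and without predicted genes. The rule also names up to 4 members of each list with the smallest adjusted p. Pln and Nkx2-5, which belong to the panel, were not found by symbol among the listed features and so could not be analysed. Myog, also of the panel, had too few counts to be tested. Several genes belong to more than 1 list, among them Myl7, Nppa, Myh7 and Gata4. Counts of list members cover tested genes only, for several lists far fewer than listed. Tested were 14 of 33 skeletal muscle, 7 of 12 ventricular, 12 of 21 endothelial, 9 of 20 neural and 8 of 17 adipocyte markers. The others were absent from the deposited table or had too few counts. A gene near 0 in 1 group could be tested through its counts in another. Of the lists, 29 had at least 5 tested members and were tested against all other genes with camera (limma 3.58.1) on voom log2 CPM, with a preset correlation of 0.01 between genes and adjustment over the 29 lists. An adjusted p of a list is from this test. It was computed again with a correlation estimated for each list, and fry was run as a test of whether the members of a list moved, on balance, one way. Shares of the counts in ribosomal protein, histone and mitochondrial genes and 4 other measures of the libraries were compared by two-sided exact permutation tests, whose smallest possible p for 5 against 5 is 0.0079, adjusted over the 7 measures within each comparison.

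The responses to MGT and MΔGΔT were set side by side by the correlation and covariance of their log2 fold changes across genes. Both use the same MEF libraries, so 100 draws without any effect gave the value to compare with, and the MEF libraries were also split between the comparisons. The computations were tested on simulated data made from the real means and library sizes, with 50 genes changed at each of 4 fold sizes. The changed genes were drawn only from genes above a low level in the second group of the comparison. The shares recovered do not cover genes with few counts there. For MGT against MEF, 64% of genes changed 1.25-fold were recovered, 84% at 1.5-fold, 98% at 2-fold and 100% at 4-fold (13202 genes). For MΔGΔT against MEF the shares were 60%, 86%, 94% and 100% (13108 genes), and for MΔGΔT against MGT 70%, 84%, 98% and 98% (13110 genes). Of the unchanged genes, 0.12%, 0.069% and 0.084% were called in these comparisons. Among 21 lists in each simulation, the shifted list was called and 0 unchanged lists were. The simulated genes vary independently, which real genes need not do. Over other splits of the libraries of the 3 comparisons, camera called a median of 7, 9 and 6 lists. These splits keep part of the difference between the groups, so they do not show how many lists are called without one.

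The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library totals without composition factors, no filter and a filter of 10 CPM in 5 libraries, a fit of only the compared groups, the replicate number as a block, stricter thresholds, the factor and mitochondrial genes left out, and each library left out in turn. Library totals implied by the RPKM values, and Gm26917 left out, were added after seeing the data. A second list of 20 leukocyte genes, without members of the fixed list of macrophage and blood markers, was written after the values of the fixed list were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.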

Results

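Mouse embryonic fibroblasts (MEF), connective tissue cells grown from embryos, were profiled by RNA-seq as a MEF group and 1 week after transduction with retrovirus in an MGT and an MΔGΔT group. MGT stands for Mef2c, Gata4 and Tbx5, transcription factors of the developing heart whose joint expression moves fibroblasts toward a cardiac muscle state. The labels do not define the symbol Δ in MΔGΔT. It is read here as a change of Mef2c and Gata4, since the series title speaks of engineered effector domains of these 2. Each of the 3 groups held 5 libraries. The counts of a library summed to between 8.21 M and 11.1 M (M, mega), with means of 9.26 ± 0.857 M in MEF, 10.4 ± 0.821 M in MGT and 10.2 ± 0.475 M in MΔGΔT (SD, n = 5). The first principal component of log2 CPM held 82.1% of the variance and ran from MEF (-57.65 to -55.90) through MGT (10.53 to 15.11) to MΔGΔT (42.55 to 45.80). The second, with 13.3%, set MGT (-23.94 to -22.74) apart from MEF (6.89 to 7.71) and MΔGΔT (13.97 to 17.98).

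The 3 factor genes were looked at first, since they check the labels. Mef2c (chromosome 13, 83504034 to 83667080, mm10) stood at 57.9 to 60.9 CPM in the 5 MEF libraries, 533 to 638 in MGT and 592 to 647 in MΔGΔT. Gata4 (chromosome 14, 63198922 to 63271692) stood at 1.92 to 3.14, 138 to 168 and 188 to 196 CPM. Tbx5 (chromosome 5, 119832668 to 119885219) stood at 3.75 to 5.36, 117 to 137 and 170 to 181 CPM. Against MEF, the log2 fold changes in MGT were 3.28 ± 0.0440 for Mef2c, 5.92 ± 0.0837 for Gata4 and 4.81 ± 0.0708 for Tbx5 (SE, n = 5 and 5). In MΔGΔT they were 3.40 ± 0.0442, 6.27 ± 0.0821 and 5.31 ± 0.0689. Between the transduced groups, Tbx5 was higher in MΔGΔT by 0.51 ± 0.0413 (adjusted p = 1.4e-13) and Gata4 by 0.34 ± 0.0444 (adjusted p = 1.7e-08), though Gata4 was not called with RPKM-implied totals (0.09, adjusted p = 0.112). Mef2c was higher by 0.12 ± 0.0375 (adjusted p = 0.00526), but not with upper-quartile factors (0.06, adjusted p = 0.152), and the sign of this small difference turned with library totals (-0.05, adjusted p = 0.231) and RPKM-implied totals (-0.13, adjusted p = 0.00758). Counts of these genes can hold viral as well as cellular transcripts, and any part of Mef2c or Gata4 that a Δ construct lacks would go uncounted.

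**Figure D1:**
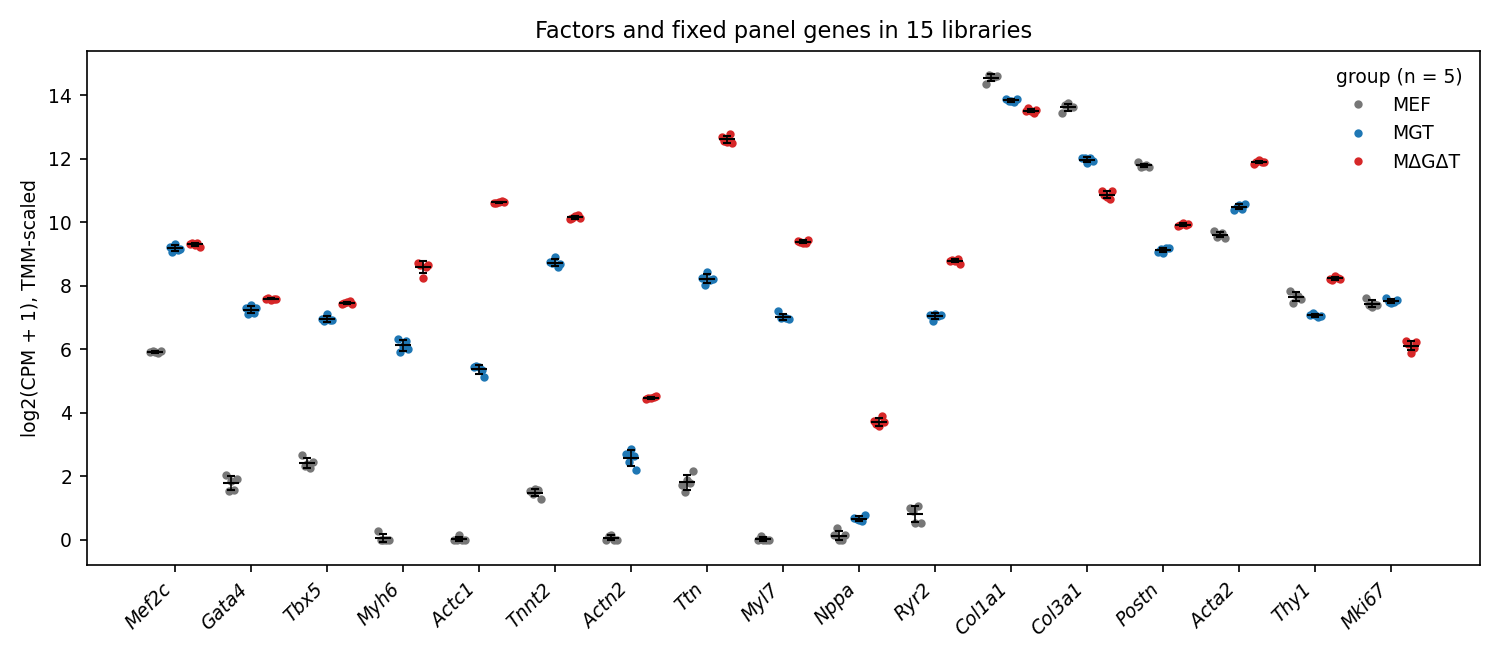
Log2(CPM + 1) of the 3 factor genes and 14 tested panel genes in each library (points), with the mean and SD of each group of 5 (black). The factor and cardiac genes lie lowest in MEF, and from Myh6 to Ryr2 each of the 5 MΔGΔT libraries lies above each MGT library.

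The first comparison, MGT against MEF, asks what the unaltered factors change in fibroblasts. Most genes of the contractile apparatus of heart muscle rose, together with most genes of calcium handling and stretch-responsive genes. Most matrix genes and fibroblast markers, interferon-response genes and markers of macrophages fell. With an estimated correlation the interferon and macrophage lists were not called (adjusted p = 0.145 and 0.0846). The cardiac troponin gene Tnnt2 (chromosome 1, 135836354 to 135852260) went from 1.81 ± 0.227 to 424 ± 36.9 CPM (SD, n = 5), a log2 fold change of 7.86 ± 0.0788 (SE, adjusted p = 1.4e-39). Ttn, which encodes the giant spring protein of the sarcomere (chromosome 2, 76703980 to 76982547), rose from 2.54 ± 0.601 to 297 ± 29.2 CPM (6.87 ± 0.136, adjusted p = 4.0e-15).

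Of 28 tested sarcomere genes, 26 rose and 1 fell in MGT, with a median log2 fold change of 6.48, or 5.38 with genes at 0 counts in MEF set to their bound (adjusted p = 2.2e-14). The one that fell was Nebl, named here after its values were seen. The atrial myosin light chain Myl7 stood at 129 ± 9.38 CPM in MGT against 1 count in all 5 MEF libraries (ratio 6010, interval 1080 to 238000). For the cardiac myosin heavy chain Myh6 and cardiac actin Actc1 the ratios were 1610 (446 to 13300) and 1880 (338 to 74400), and Myl4, Ldb3 and Des rose by 7.28, 6.56 and 5.02. Reads shared with the related genes Myh7, Acta1 and Acta2 make single values of Myh6 and Actc1 less certain. Of 30 genes for calcium handling and ion channels, 21 rose and 6 fell (median 1.49, adjusted p = 0.000154). They include the ryanodine receptor Ryr2, which rose by 7.38 ± 0.0988 to 131 ± 8.58 CPM, the calsequestrin Casq2 (6.34 ± 0.117) and the calcium pump Atp2a2 (1.39 ± 0.0316). Of 9 natriuretic and stretch-responsive genes, 7 rose and 0 fell (median 2.06, adjusted p = 0.00365), among them Ankrd1 with 4.75 ± 0.0882. The natriuretic peptide gene Nppa stayed low, at 0.585 ± 0.0795 CPM against 0.1 ± 0.118 (2.31 ± 0.526, adjusted p = 0.000226). Myh7, the slow cardiac myosin, was at least 37.7-fold higher.

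Markers of heart subtypes moved less evenly. Of 9 atrial markers, 7 rose and 1 fell (median 2.31, adjusted p = 0.00292), and of 7 ventricular markers 5 rose and 2 fell (median 0.88, adjusted p = 0.0313, but 0.145 with an estimated correlation and 0.0602 with library totals). Sln, an atrial regulator of the calcium pump, was at least 143-fold higher, while the ventricular troponin gene Tnni3 rose by 4.52 ± 0.235 to 7.64 ± 0.896 CPM. Among 14 pacemaker markers, 8 rose and 3 fell (adjusted p = 0.338), with the pacemaker channel Hcn4 up by 3.97 ± 0.204. Of 21 cardiac transcription factors and cofactors, 12 rose and 5 fell (median 0.42, adjusted p = 0.0412, and adjusted p = 0.145 with an estimated correlation). Smyd1, a muscle methyltransferase, rose by 6.51 ± 0.3 and the cardiac coactivator Myocd by 2.72 ± 0.142. The list's call was also lost with library totals (adjusted p = 0.0713) and without MEF replicate 3 (adjusted p = 0.0567). Of 14 tested skeletal muscle markers, from a list of 33, 10 rose and 2 fell (median 2.01, adjusted p = 0.0633), and 10 and 3 when adjusted over the list alone. Among genes outside the lists, the potassium channel Kcnc4 stood at 149 ± 7.31 CPM against 2 counts in MEF (ratio 3460, interval 957 to 28600), and the receptor gene Gpr83 was at least 337-fold higher. Actn2, a Z-disc protein, had a ratio of 117 (32.1 to 971).

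Fibroblast genes fell. Of 36 extracellular matrix genes, 31 fell and 3 rose (median -1.13, adjusted p = 2.3e-17), and of 24 fibroblast identity genes 21 fell and 1 rose (median -0.61, adjusted p = 1.6e-07), or 21 and 2 adjusted over the list alone. Col3a1 went from 12600 ± 1050 to 4000 ± 195 CPM (-1.65 ± 0.0646, adjusted p = 7.0e-12) and Col1a1 from 24000 ± 1770 to 14600 ± 362 (-0.72 ± 0.0381). Postn, a matrix protein of activated fibroblasts (chromosome 3, 54361109 to 54391037), fell by 2.66 on the log2 scale, from 3520 ± 153 to 558 ± 29.1 CPM. Thy1 fell by 0.59, Cd248 by 1.89 and Fap by 1.36, and the one gene of the identity list that rose was Vim (0.88 ± 0.0303). Smooth muscle and myofibroblast markers rose for the most part, with 12 up and 3 down of 16 (median 0.65, adjusted p = 0.00119, and adjusted p = 0.11 with an estimated correlation), including Cthrc1 (2.94 ± 0.0490) and Acta2 (0.87 ± 0.0387). Of 24 WNT and Notch genes, 13 fell and 8 rose (median -0.18, adjusted p = 0.0253, and adjusted p = 0.145 with an estimated correlation), with Dkk2 down by 2.09 and Sfrp2 by 1.37. Of the 21 TGF-beta genes, 8 rose and 10 fell (adjusted p = 0.633 by camera, and 0.0268 by fry, downward). Their median was 0.01, -0.02 with upper-quartile factors, and their mean -0.11. Tgfb2 rose by 1.26 and Ltbp2 fell by 1.31.

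All 15 macrophage and blood markers fell in MGT (median -3.52, adjusted p = 8.0e-13, and adjusted p = 0.0846 with an estimated correlation). The leukocyte surface gene Ptprc went from 64.3 ± 5.54 to 5.58 ± 1.24 CPM, and Cd68 from 167 ± 11 to 11.6 ± 3.18. Of the largest falls, Ptgds (-5.90 ± 0.165) encodes a prostaglandin synthase, and Ms4a7 (-4.42 ± 0.102), Ptafr (-4.36 ± 0.145) and Fcgr1 (-4.18 ± 0.175) are expressed in macrophages. Beside these falls, 26 of 28 interferon-response genes fell and 1 rose (median -0.70, adjusted p = 6.5e-05, and adjusted p = 0.145 with an estimated correlation). Of 22 inflammatory genes, 14 fell and 4 rose (median -0.60, adjusted p = 0.006, and adjusted p = 0.145 with an estimated correlation). Icam1 fell by 1.17, while Ptgs2, which makes prostaglandins, rose by 1.16 ± 0.0658. Of 21 immediate early and stress genes, 16 fell and 2 rose, or 18 and 2 adjusted over the list alone (median -0.45, adjusted p = 0.00119, and adjusted p = 0.31 with an estimated correlation), with Klf2 down by 1.59. Adipocyte genes moved with them, since 6 of 8 fell and 1 rose, or 6 and 2 adjusted over the list alone (median -0.97, adjusted p = 0.014, and adjusted p = 0.0846 with an estimated correlation). Lpl, a lipase that macrophages also make, went from 1210 ± 44.5 to 70.5 ± 13.9 CPM.

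Cell cycle genes were slightly higher in MGT, with 23 of 38 up and 5 down (median 0.27, adjusted p = 0.014, and adjusted p = 0.307 with an estimated correlation). Cenpa rose by 1.46 ± 0.0797 and Cdc20 by 0.74 ± 0.0722, Pcna fell by 0.70, and Mki67 was at 182 ± 7.63 against 172 ± 13.1 CPM (0.08 ± 0.0524, adjusted p = 0.167). Of 21 p53 and senescence genes, 14 rose and 4 fell (median 0.52, adjusted p = 0.00119, and adjusted p = 0.145 with an estimated correlation), with the cell cycle inhibitor Cdkn1a up by 1.12 ± 0.0386. Glycolysis genes rose, 20 of 22 with 2 down (median 0.57, adjusted p = 7.5e-07, and adjusted p = 0.11 with an estimated correlation), led by the muscle enolase Eno3 (4.34 ± 0.0629). Of 36 oxidative phosphorylation genes, 18 rose and 2 fell, or 18 and 1 adjusted over the list alone, by small amounts (median 0.14, adjusted p = 0.0203, and adjusted p = 0.569 with an estimated correlation). Of 30 fatty acid and cardiac metabolism genes, 16 rose and 8 fell (median 0.24, adjusted p = 0.0972). The oxygen store myoglobin, Mb, had 470 counts in MGT against 1 in MEF (ratio 397, interval 70.9 to 15700), and the fatty acid carrier Cd36 fell by 3.60.

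In all, 4120 genes were higher and 4040 lower in MGT than in MEF, 61.2% of the 13328 tested, and 915 and 1251 of these by at least 2-fold. With library totals in place of composition factors the counts were 5181 and 3276. The 2 groups did not overlap for 6099 genes, where chance gives 0.79%. Camera called 19 of the 29 lists, 11 up and 8 down, and 6 calls held with an estimated correlation. Other splits of the same 10 libraries gave a median of 7 and up to 17 called lists. In all 3 comparisons the numbers of list members are the same adjusted over the list alone unless another count is given. MEF replicate 1 stood apart from the other MEF libraries in a chi-square comparison of replicates (4.67 to 7.43 per degree of freedom, against at most 4.04 for the remaining pairs), and without it the counts were 4087 and 3996. No vector-only control is named, so transduction and the factors cannot be told apart.

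**Figure D2:**
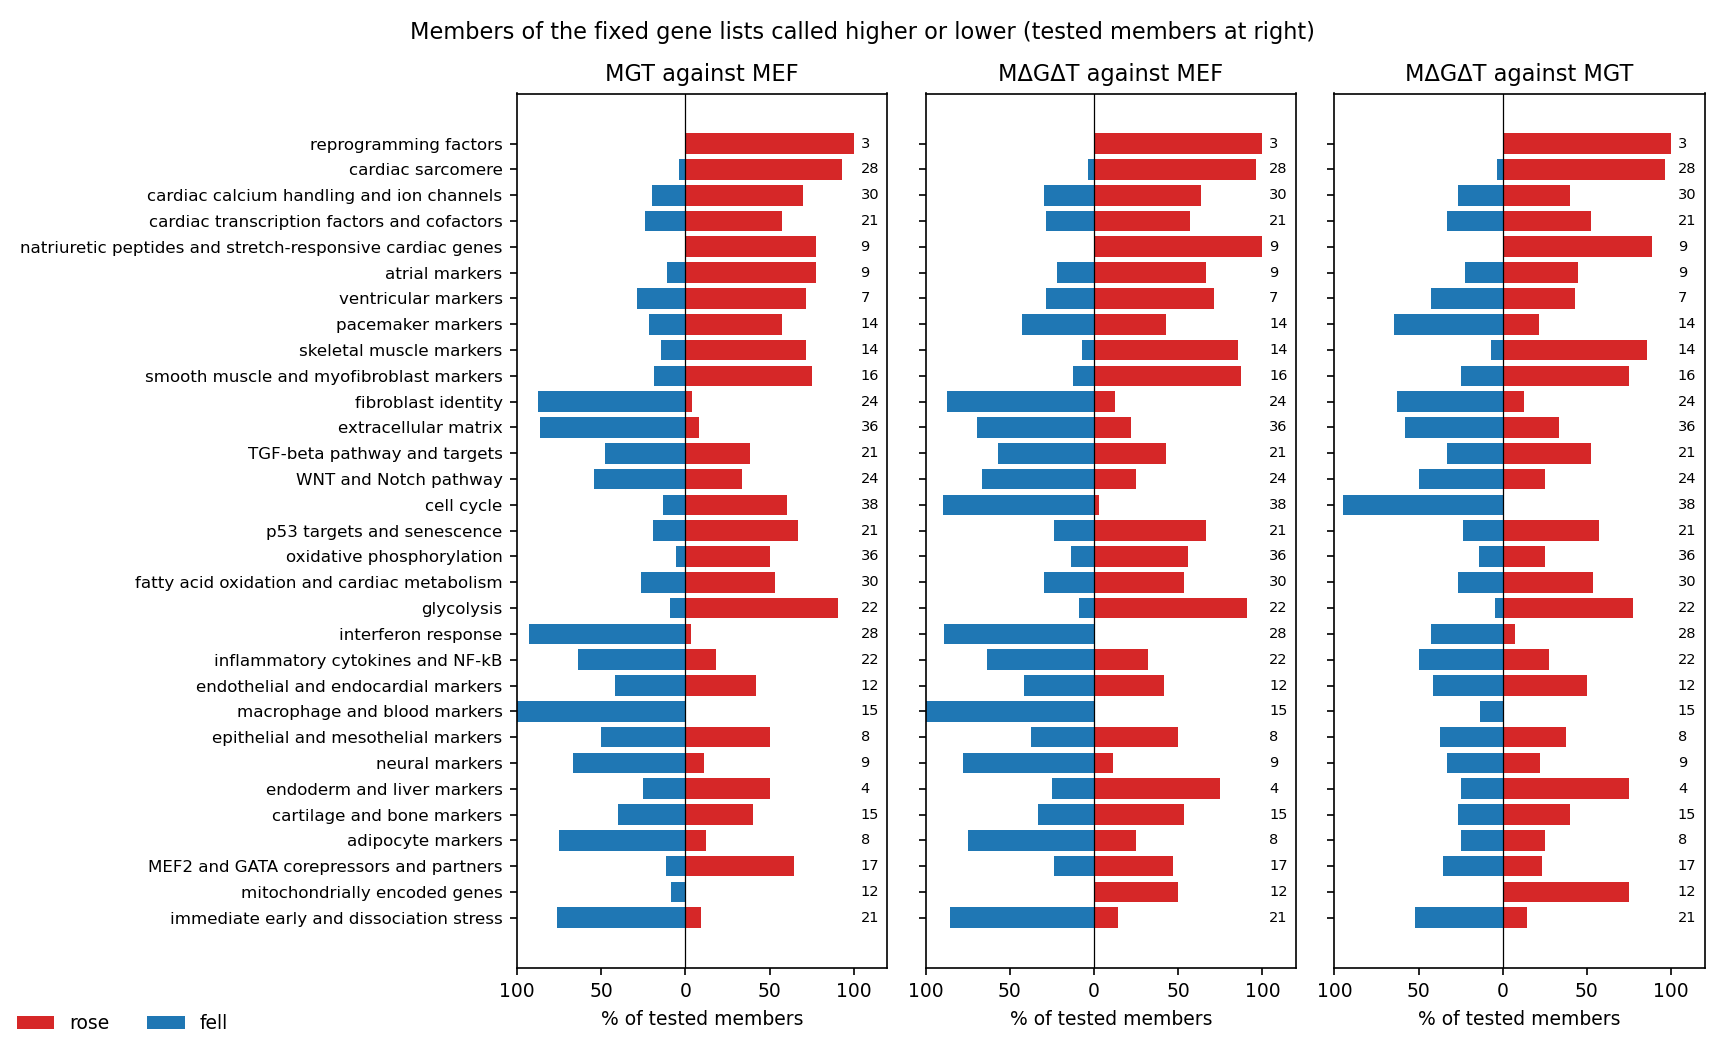
Percent of the tested members of each gene list that rose (red, to the right) or fell (blue, to the left) in each comparison, with the number tested at the right of each panel. Of 28 sarcomere genes, 26, 27 and 27 rose in the 3 comparisons, and of 38 cell cycle genes 5, 34 and 36 fell, while other lists shift with the scaling, such as oxidative phosphorylation in MΔGΔT against MGT (median 0.03, -0.14 with library totals).

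The second comparison, MΔGΔT against MEF, asks what the second form of the factor set changes in the same cells. Most heart muscle genes rose, some of them to high levels. Most fibroblast and matrix genes and all tested macrophage markers fell, and so did most cell cycle genes. With an estimated correlation the macrophage and cell cycle lists were not called (adjusted p = 0.114 and 0.0581). Library totals and RPKM-implied totals lower every log2 fold change of this comparison alike, by about the shifts of the median of all genes (-0.10 and -0.24). Ttn went from 2.54 ± 0.601 to 6240 ± 541 CPM (SD, n = 5), a log2 fold change of 11.27 ± 0.132 (SE, adjusted p = 4.7e-18). Actc1 (chromosome 2, 114047282 to 114053548) stood at 1580 ± 15.9 CPM against 1 count in all MEF libraries (ratio 73300, interval 13200 to 2900000).

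Of the 28 sarcomere genes, 27 rose and 1 fell in MΔGΔT (median 9.43, or 8.58 at the bounds, adjusted p = 1.2e-14). Myl7 had a ratio of 31000 (5570 to 1220000), Myh6 of 8870 (2460 to 73300) and Actn2 of 493 (136 to 4080). Tnnt2 reached 1140 ± 36.6 CPM (9.29 ± 0.0766), Myl4 1700 ± 36.1 CPM and Ldb3 441 ± 4.20 CPM, and Myoz2, a Z-disc gene, was at least 545-fold higher. Of 30 genes for calcium handling and ion channels, 19 rose and 9 fell (median 2.11, adjusted p = 0.00356, and adjusted p = 0.0584 with an estimated correlation), with Ryr2 up by 9.12 ± 0.0886, Casq2 by 9.68 ± 0.0849 and Atp2a2 by 2.14 ± 0.0322. All 9 natriuretic and stretch-responsive genes rose (median 6.66, or 5.50 at the bounds, adjusted p = 1.4e-05). Nppa reached 12.1 ± 1.08 CPM (6.66 ± 0.262, adjusted p = 4.9e-24), Ankrd1 rose by 7.05 ± 0.0779, and Csrp3, a stretch sensor of muscle, was at least 381-fold higher. Of 9 atrial markers, 6 rose and 2 fell (median 4.17, adjusted p = 0.0223, and adjusted p = 0.0713 with an estimated correlation). Of 7 ventricular markers, 5 rose and 2 fell (median 0.95, adjusted p = 0.0758), with Myh7 at least 193-fold higher and the ventricular factor Hey2 down by 3.27. Pacemaker markers went both ways, 6 up and 6 down of 14 (median -0.22, mean 0.27, adjusted p = 0.878, but 6 and 8 with RPKM-implied totals, median -0.46), with Hcn4 up by 3.50 and Cacna1g down by 1.92. Cardiac transcription factors had 12 up and 6 down of 21 (median 0.73, adjusted p = 0.0437, and adjusted p = 0.157 with an estimated correlation). This call was lost without MEF replicate 2 (adjusted p = 0.05). Myocd rose by 5.68 ± 0.0980 to 75.4 ± 1.27 CPM.

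Most tested skeletal and smooth muscle markers rose as well. Of 14 tested skeletal muscle markers, from a list of 33, 12 rose and 1 fell (median 3.84, adjusted p = 0.00126, and adjusted p = 0.0581 with an estimated correlation). The skeletal light chain Myl1 stood at 110 ± 11.7 CPM against 3 counts in MEF (ratio 1700, interval 582 to 8260), and Myh8, a perinatal myosin, fell by 2.35. Myog, the muscle differentiation factor, had 5 to 14 counts per MΔGΔT library, 0 to 2 in MGT and 0 in each MEF library. Smooth muscle and myofibroblast markers had 14 up and 2 down of 16 (median 1.84, adjusted p = 7.0e-06), including Acta2, from 779 ± 48.7 to 3790 ± 112 CPM, Tpm2 (2.70 ± 0.0499) and Itga8 (2.63 ± 0.0367). Postn fell by 1.86. Of 24 fibroblast identity genes, 21 fell and 3 rose (median -1.38, adjusted p = 8.6e-07). Fap fell by 3.05 and Cd248 by 2.56, while Thy1 rose by 0.59 ± 0.0463 and Vim by 1.69 ± 0.0308. Of 36 matrix genes, 25 fell and 8 rose (median -1.40, adjusted p = 1.1e-07), with Col3a1 down by 2.75 to 1870 ± 143 CPM, Col1a2 by 1.74 and Col1a1 by 1.04. The largest falls included Ptgds (-6.50 ± 0.186), the growth regulator Dlk1 (-5.87 ± 0.190) and the angiotensin receptor gene Agtr2 (-5.20 ± 0.172). TGF-beta genes had 9 up and 12 down of 21 (median -0.25, or -0.49 with RPKM-implied totals, mean 0.23, adjusted p = 0.888), with Ctgf and Tgfb2 up by 2.81 and 2.60 and the receptor Tgfbr2 down by 1.34. WNT and Notch genes had 16 down and 6 up of 24, or 16 and 7 adjusted over the list alone (median -0.67, adjusted p = 0.0157, and adjusted p = 0.142 with an estimated correlation), with Notch1 down by 1.39.

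Of 38 cell cycle genes, 34 fell and 1 rose, or 35 and 1 adjusted over the list alone (median -0.87, adjusted p = 3.4e-08, and adjusted p = 0.0581 with an estimated correlation). Mki67, a marker of dividing cells (chromosome 7, 135689784 to 135716361), went from 172 ± 13.1 to 68.4 ± 6.75 CPM (-1.33 ± 0.0571, adjusted p = 5.1e-18). The replication genes Mcm3 and Pcna fell by 1.40 and 1.31. Histone genes took 0.0508 ± 0.00163% of the counts against 0.0860 ± 0.0104% in MEF, and ribosomal protein genes 1.04 ± 0.0311% against 1.64 ± 0.131% (exact permutation p = 0.0079 for each, adjusted p = 0.014). Of 21 p53 and senescence genes, 14 rose and 5 fell (median 0.90, adjusted p = 0.00227, and adjusted p = 0.161 with an estimated correlation). Cdkn1a rose by 1.89 ± 0.0388 and Cdkn2b, also an inhibitor of the cell cycle, by 1.69. Glycolysis genes had 20 up and 2 down of 22 (median 0.83, adjusted p = 1.2e-07, and adjusted p = 0.0795 with an estimated correlation), with Eno3 up by 5.82 ± 0.0597 and the hexokinase Hk2 by 2.14 ± 0.0477. Oxidative phosphorylation genes had 20 up and 5 down of 36, or 19 and 5 adjusted over the list alone (median 0.16, -0.08 with RPKM-implied totals, adjusted p = 0.0396, and adjusted p = 0.603 with an estimated correlation). With RPKM-implied totals 7 rose and 14 fell. The call was lost with library totals (adjusted p = 0.0931) and without MEF replicate 1 (adjusted p = 0.0676), MEF replicate 5 (adjusted p = 0.0657) or MΔGΔT replicate 5 (adjusted p = 0.054). Fatty acid and cardiac metabolism genes had 16 up and 9 down of 30 (median 0.31, adjusted p = 0.137, but 13 up and 12 down with a median of 0.07 with RPKM-implied totals), with the insulin-responsive glucose carrier Slc2a4 up by 3.43 ± 0.1.

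Macrophage and blood markers fell in MΔGΔT too, 15 of 15 (median -3.74, adjusted p = 2.2e-09, and adjusted p = 0.114 with an estimated correlation), and Cd68 stood at 11.8 ± 1.02 CPM. Beside them 25 of 28 interferon-response genes fell and 0 rose (median -1.03, adjusted p = 4.6e-05, and adjusted p = 0.142 with an estimated correlation). Ifit3 fell by 2.71 and Ifit3b (-3.49) with it, a pair of near-identical genes that can share reads. Inflammatory genes had 14 down and 7 up of 22 (median -1.23, adjusted p = 0.0231, but 0.197 with an estimated correlation and 0.0543 with library totals), with Tnfaip3 down by 2.16 and Csf1 by 1.37, but Ptgs2 and the cytokine Lif up by 2.87 and 2.65. Immediate early and stress genes had 18 down and 3 up of 21 (median -0.83, adjusted p = 0.000802, and adjusted p = 0.291 with an estimated correlation), among them Klf2 (-2.80). Of 8 adipocyte genes, 6 fell and 2 rose (median -0.85, adjusted p = 0.0556, and 0.0479 and 0.0486 without MEF replicate 1 or 3), Lpl by 4.25.

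In all, 4819 genes were higher and 4818 lower in MΔGΔT than in MEF, 72.3% of those tested, 1424 and 1630 of them by at least 2-fold. With library totals the counts were 3967 and 5798, with RPKM-implied totals 2927 and 7159, and without MEF replicate 1 they were 4821 and 4797. The 2 groups did not overlap for 7795 genes, where chance gives 0.79%. Camera called 18 of 29 lists, 10 up and 8 down, and 5 calls held with an estimated correlation, while other splits gave a median of 9 and up to 15.

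The responses to MGT and to MΔGΔT ran largely in parallel. Of the tested genes, 3206 were higher in both and 3156 lower in both, where independent lists would share 1490 and 1460. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.865, against 0.520 in simulated groups without effect that shared the same MEF libraries. The covariance was 1.07 against 0.00782, and the slope of the MΔGΔT change on the MGT change was 1.11. Splitting the MEF libraries between the comparisons left r at 0.850 and 0.854. A further 335 genes rose in MGT and fell in MΔGΔT against MEF, and 277 did the reverse.

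**Figure D3:**
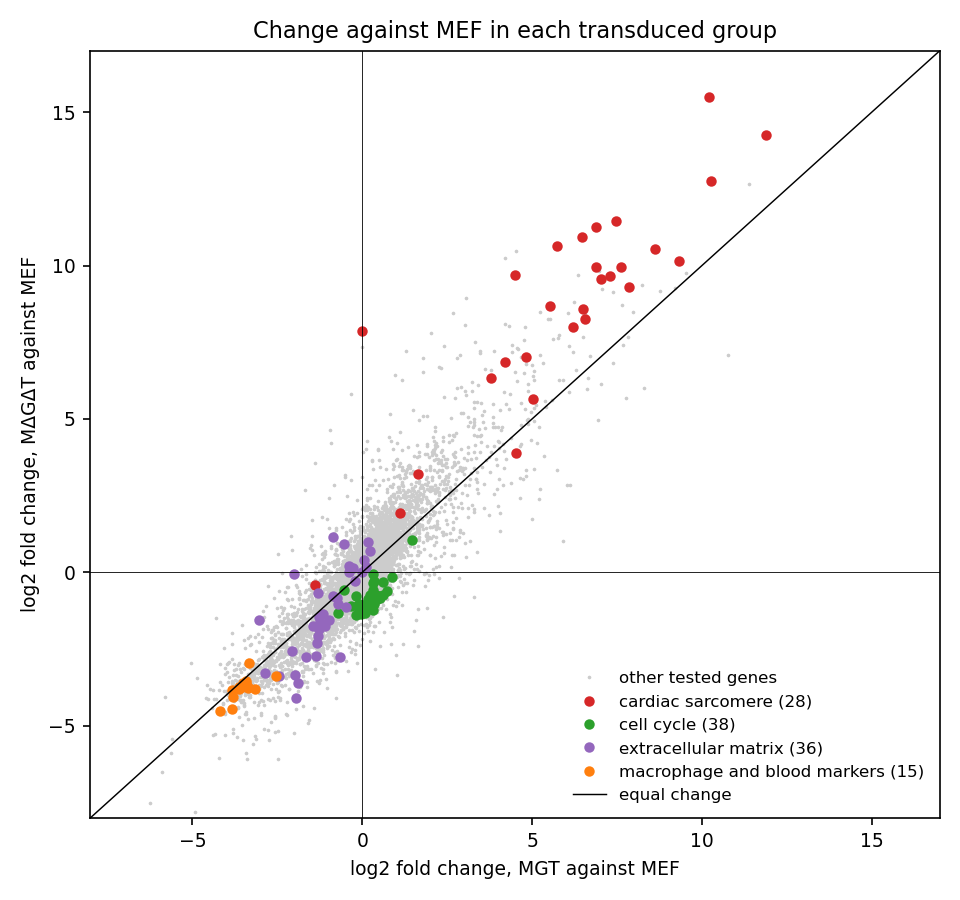
Log2 fold change of each tested gene (points) in MΔGΔT against MEF (vertical) and in MGT against MEF (horizontal), with 4 gene lists in colour and a line of equal change. Sarcomere genes lie above the line for 27 of 28 members, and all 38 cell cycle genes lie below it.

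The third comparison, MΔGΔT against MGT, asks how the 2 forms of the factor set differ. Most sarcomere genes rose further, and with them most stretch-responsive, skeletal and smooth muscle genes. Most cell cycle and fibroblast identity genes fell, though the fibroblast list was not called with an estimated correlation (adjusted p = 0.186). The 2 other totals lower every log2 fold change of this comparison alike, by about the shifts of the median of all genes (-0.17 with library totals and -0.26 with RPKM-implied totals), so list medians near 0 depend on the scaling. Ttn was higher by a log2 fold change of 4.39 ± 0.0829 (SE, adjusted p = 3.9e-15, n = 5 and 5), at 6240 ± 541 against 297 ± 29.2 CPM (SD). Actc1 was higher by 5.29 ± 0.0491 (adjusted p = 1.5e-42) and Mki67 was lower (-1.41 ± 0.0566, adjusted p = 2.9e-18).

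Of 28 sarcomere genes, 27 rose and 1 fell (median 2.36, adjusted p = 3.0e-23). The one that fell was Tnni3, by 0.63 on the log2 scale, which was named in this comparison after its values were seen. The cardiac myosin-binding protein Mybpc3 went from 2.67 ± 0.761 to 99.4 ± 2.44 CPM (5.19 ± 0.0907), and Xirp2 rose by 4.89 ± 0.131. Tnnt2 rose by 1.43 ± 0.0415, Myh6 by 2.47 ± 0.0985, Myl7 by 2.37 ± 0.0420 and Actn2 by 2.08 ± 0.104. Of 9 stretch-responsive genes, 8 rose and 0 fell (median 2.35, adjusted p = 3.1e-06), with Nppa up by 4.35 ± 0.183 and Csrp3 by 4.48 ± 0.130. Skeletal muscle markers had 12 up and 1 down of 14 (median 1.70, adjusted p = 0.000139). Under the naming rule Myl1 (chromosome 1, 66924295 to 66945404) had the largest rise, from 1.81 ± 0.526 to 110 ± 11.7 CPM (5.94 ± 0.108). Myh1, Myh3 and Ryr1 rose by 3.32, 3.31 and 3.19. Smooth muscle and myofibroblast markers had 12 up and 4 down of 16 (median 1.22, adjusted p = 9.9e-06), with Acta2 up by 1.41 ± 0.0387, Cnn1 by 2.53 ± 0.0766 and Postn by 0.80 ± 0.0348.

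Several other lists of heart genes went both ways. Calcium handling and ion channel genes had 12 up and 8 down of 30, and their median of 0.17 came to 0.002 with library totals and -0.08 with RPKM-implied totals (adjusted p = 0.0775, but 0.0105 with library totals). Casq2 rose by 3.34 ± 0.0435, Ryr2 by 1.74 ± 0.0433 and Atp2a2 by 0.74 ± 0.0308. Cardiac transcription factors had 11 up and 7 down of 21, with a median of 0.15 that turned to -0.02 with library totals and -0.11 with RPKM-implied totals (adjusted p = 0.5), where 8 and 7 rose and 9 and 9 fell. Myocd rose by 2.95 ± 0.0659 (adjusted p = 1.2e-31). Atrial markers had 4 up and 2 down of 9 (median 0.38, adjusted p = 0.0775, but 0.0131 with library totals). Ventricular markers had 3 up and 3 down of 7, with a median of 0.07 that turned to -0.10 and -0.19 with the same totals (adjusted p = 0.621), and the gap junction gene Gja1 fell by 0.76. Pacemaker markers had 9 down and 3 up of 14 (median -0.39, -0.56 and -0.64 with the same totals, adjusted p = 0.0775), with Bmp4 down by 1.16.

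All but 2 of the 38 cell cycle genes fell, 36 with 0 up, or 37 with 0 up adjusted over the list alone (median -1.12, adjusted p = 1.7e-19). The topoisomerase Top2a went from 138 ± 6.27 to 55.7 ± 5.23 CPM (-1.31 ± 0.0482), and the mitotic kinesins Kif11 and Kif20a fell by 1.35 each. Histone genes took 0.0508 ± 0.00163% of the counts against 0.0955 ± 0.00580% in MGT, and ribosomal protein genes 1.04 ± 0.0311% against 1.48 ± 0.0513% (exact permutation p = 0.0079 for each, adjusted p = 0.018). The p53 and senescence list had 12 up and 5 down of 21, or 13 and 5 adjusted over the list alone (median 0.28, adjusted p = 0.0327, and adjusted p = 0.401 with an estimated correlation), a call lost without MΔGΔT replicate 3 (adjusted p = 0.0582). With library totals 10 rose and 7 fell (median 0.11), and with RPKM-implied totals 8 and 7 (median 0.02). Cdkn2b rose by 1.18 ± 0.0466 and Cdkn1a by 0.77 ± 0.0368, and Sesn1 fell by 1.28. Glycolysis genes had 17 up and 1 down of 22, with a median of 0.25 that came to -0.003 with RPKM-implied totals (adjusted p = 0.000111, and adjusted p = 0.254 with an estimated correlation), and Hk2 rose by 1.70 ± 0.0449. With library totals 11 glycolysis genes rose and 4 fell, and with RPKM-implied totals 7 and 5. Mitochondrially encoded genes had 9 up and 0 down of 12 (median 0.52, adjusted p = 0.0271, and adjusted p = 0.424 with an estimated correlation), with mt-Co1 up by 0.62 ± 0.0968. With library totals 6 of the 12 rose (median 0.35), and with RPKM-implied totals 5 (median 0.26). Their share of the counts was 0.6 ± 0.0721% against 0.468 ± 0.0450% (exact permutation p = 0.016, adjusted p = 0.028). Nuclear oxidative phosphorylation genes had 9 up and 5 down of 36, or 8 and 4 adjusted over the list alone (adjusted p = 0.861), with a median of 0.03 that was -0.03 with upper-quartile factors, -0.14 with library totals (1 up, 18 down) and -0.22 with RPKM-implied totals (1 up, 25 down). Fatty acid and cardiac metabolism genes had 16 up and 8 down of 30, or 16 and 9 adjusted over the list alone (adjusted p = 0.424), with a median of 0.12 that turned to -0.06 and -0.14 with the same totals (10 up and 13 down, and 8 and 16). Slc2a4 rose by 1.77 ± 0.0771, and Acaa2 fell by 1.32.

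Of 24 fibroblast identity genes, 15 fell and 3 rose (median -0.72, adjusted p = 0.000589, and adjusted p = 0.186 with an estimated correlation). Fap and Sfrp1 fell by 1.70 and 1.26, and Thy1 rose by 1.17 ± 0.0471. Matrix genes had 21 down and 12 up of 36 (median -0.26, adjusted p = 0.0775), but 25 down and 11 up with library totals (median -0.43) and 25 and 10 with RPKM-implied totals (median -0.51). Col3a1 fell by 1.10, but Thbs1 went from 3180 ± 107 to 12800 ± 510 CPM (2.02 ± 0.0318), and Col12a1 rose by 1.47 ± 0.0338. TGF-beta genes had 11 up and 7 down of 21, with a median of 0.25 that came to -0.01 with RPKM-implied totals (adjusted p = 0.0775, but 0.0348 with library totals). With library totals 10 of them rose and 9 fell, and with RPKM-implied totals 8 and 9. Inhba and Ctgf rose by 2.10 and 1.61. WNT and Notch genes had 12 down and 6 up of 24 (median -0.22, adjusted p = 0.121), but 15 and 16 down with library totals and RPKM-implied totals (medians -0.39 and -0.48), with Axin2 up by 1.39. Of 15 macrophage and blood markers 2 were down, or 0 adjusted over the list alone (median -0.21, adjusted p = 0.366), but 4 with library totals (median -0.385) and 6 with RPKM-implied totals (median -0.47). Lyz2 was at 184 ± 30.2 against 141 ± 35.3 CPM (adjusted p = 0.0859, but 0.0105 with limma-voom and 0.0402 without MGT replicate 1). Interferon-response genes had 12 down and 2 up of 28 (median -0.30, adjusted p = 0.0891), with 17 and 18 down with library totals and RPKM-implied totals, inflammatory genes 11 down and 6 up of 22, or 11 and 7 adjusted over the list alone (median -0.24, adjusted p = 0.197), with 13 down under either of these totals, and immediate early and stress genes 11 down and 3 up of 21 (median -0.34, adjusted p = 0.0507, but 0.0241 to 0.0479 without any of 6 single libraries), with 14 and 16 down under these totals. Il33 and Ifit3 fell by 2.07 each. The largest falls under the naming rule included the receptor genes Gpr165 (-4.37 ± 0.197) and Gria1 (-3.84 ± 0.155), and Gpr83, which rose with MGT, was lower by 3.69.

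In all, 4056 genes were higher and 3706 lower in MΔGΔT than in MGT, 58.2% of those tested, 694 and 640 of them by at least 2-fold. With library totals, which moved the median of all genes by -0.17, the counts were 2436 and 6200, and with RPKM-implied totals 1869 and 7281, so that the balance between rises and falls depends on the scaling. The 2 groups did not overlap for 6042 genes, where chance gives 0.79%. Camera called 9 of 29 lists, 7 up and 2 down, and 5 calls held with an estimated correlation, while other splits of the same 10 libraries gave a median of 6 and up to 13. Of the 915 genes at least 2-fold higher in MGT than in MEF, 496 rose further in MΔGΔT and 263 fell. Choosing such genes with MGT replicates 1 and 2 and comparing the remaining 3 with MΔGΔT gave 476 and 245 of 899. Of all 4120 genes higher in MGT, 58.6% lay higher still in MΔGΔT (59.1% in the split), and of the 4040 lower genes 45.5% lay higher. With library totals the first share was 37.1%.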

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

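The tests of library scaling and of the amount of factor RNA were chosen only after the result was seen. The tests with a second leukocyte list and with GC content and gene length were chosen after the patterns they bear on were seen but before their own values were, except that the fall of Cd300a, 1 of the 20 genes of that list, had been seen.

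Macrophage and blood markers, which fibroblasts are not known for, fell in both transduced groups by medians of -3.52 and -3.74. Over 4 other scalings and both comparisons the least negative median was -3.44, so none of these scalings accounts for the fall. They moved the median of all genes by only -0.237 to 0.0769, so they could not have removed it. All 20 genes of the second leukocyte list, which has 0 genes in common with the fixed one, fell in both comparisons, with medians of -3.29 (SD 0.542) and -3.36 (SD 0.415), at most 0.38 from the fixed list (SD 0.373 and 0.383), and the most abundant gene of each list, Lyz2 and Ctss, went from 1429 and 208 CPM in MEF to 141 and 20.3 in MGT. This is consistent with a share of leukocytes in the MEF libraries that was 9.77 to 13.3 times higher than in the transduced ones, and no sort of the cells is named in the labels. It stays open whether transduction, culture or the factors lowered that share, whether remaining leukocytes changed their expression, and how many of the listed genes fibroblasts also express.

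Cell cycle genes were lower in MΔGΔT than in MGT by a median of -1.12. Under 4 other scalings their median was -1.12 to -1.37. All 4 lower the log2 fold changes of this comparison, so they could not have brought the median toward 0 and do not test library scaling. After a trend with GC content and gene length was removed (SD of the trend 0.0271), the median of the 38 members was -1.13 (SD 0.332), which argues against that bias as the cause. A lower rate of division in MΔGΔT may account for the pattern, as a hypothesis found in the same data. Differences in cell density or time of harvest were not tested.

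Sarcomere genes were higher in MΔGΔT than in MGT by a median of 2.36. Under 4 other scalings the lowest median was 2.11, so none of these scalings accounts for the rise. They moved the median of all genes by only -0.256 to -0.0057, so they could not have removed it. After the trend with GC content and gene length was removed, the median was 2.37 (SD 1.75), which argues against that bias as the cause. If the response were in proportion to the amount of factor RNA, members would rise by no more than the factors, whose largest rise was 0.51 for Tbx5. Instead 27 of 28 members (96.4%) rose by more than that by over 2 SE. An effect of the altered factors is a hypothesis that these values leave open, and so may be a steeper than proportional response to factor dose, or viral transcripts of Mef2c and Gata4 that went uncounted. The libraries are of bulk RNA, so a change within cells and a change in the share of cells that express these genes cannot be told apart.

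No other split tried came near the numbers of called genes. Every other split mixes the groups, which widens the fitted spread, so few calls were bound to result. The splits therefore cannot exclude chance differences between cultures, since the replicates may not be separate cultures. Among 100 of the 126 splits of the 10 libraries in each comparison, the real one gave 8160 genes in MGT against MEF (highest other 2), 9637 in MΔGΔT against MEF (highest other 1) and 7762 in MΔGΔT against MGT (highest other 0). In each case 1 split, the real one, reached that number. The 19 lists called in MGT against MEF (median of the others 7, highest other 17) were reached by 1 split, the real one. The same held for the 18 in MΔGΔT against MEF (median of the others 9, highest other 15). In MΔGΔT against MGT 9 lists were called. Of 100 splits, 26 called as many, the real one included (median of the others 6, highest other 13). Every other split keeps part of the difference between the groups, so in no comparison can these numbers of lists show or exclude chance.

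Of 72 sets of 5 values, 1 for each measure or gene and group, 9 held a value far from the others. Chance gives about 3.6 for normally spread values. Ribosomal protein genes took 1.57% of the counts in MGT replicate 2 and 1.45 to 1.48% in the other MGT libraries. Histone genes took 0.068% in MEF replicate 1 and 0.0861 to 0.0934% in the other MEF libraries. Tbx5 stood at 137 CPM in MGT replicate 3 and at 117 to 122 in the others. Myl7 stood at 145 CPM in MGT replicate 1 (others 122 to 128), and Ryr2 at 116 in MGT replicate 2 (others 132 to 138). Col1a1 stood at 20900 CPM in MEF replicate 1 (others 24200 to 25200). A few counts in 1 MEF library set Myh6 in replicate 1 (0.202 CPM), Actc1 in replicate 3 (0.112) and Myl7 in replicate 2 (0.0959) apart from 0 in the other MEF libraries. Any count beside 0 in all the others is flagged, so the chance number does not cover these sets.

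Thy1 moved in opposite directions against MEF, -0.59 in MGT and 0.59 in MΔGΔT, and the difference of 1.17 between them passed the test. The same held for 612 genes, of which 335 were higher in MGT and lower in MΔGΔT than in MEF, and 277 the reverse. The library total that the RPKM values imply, over the total of the listed counts, was 1.05 ± 0.0392 in MΔGΔT, 0.991 ± 0.0284 in MGT and 0.952 ± 0.0371 in MEF, relative to the mean library (exact permutation p = 0.0079 for MΔGΔT against MEF, adjusted p = 0.014).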

How the results depend on the processing

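The tests with RPKM-implied totals and without Gm26917 were chosen only after the result was seen. DESeq2 gave 4125 and 3898 higher and lower genes in MGT against MEF, 4848 and 4835 in MΔGΔT against MEF and 3884 and 3635 in MΔGΔT against MGT, and limma-voom 4133 and 4032, 4819 and 4796, and 4074 and 3687. Upper-quartile factors gave 3777 and 4341, 4063 and 5671, and 3402 and 4474, and at least 10 CPM in 5 libraries gave 3299 and 3056, 3695 and 3757, and 3136 and 3155. A change of at least 2-fold as well gave 915 and 1251 genes for MGT against MEF, 1424 and 1630 for MΔGΔT against MEF, and 694 and 640 for MΔGΔT against MGT, fewer by construction. Library totals gave 2436 higher and 6200 lower genes in MΔGΔT than in MGT, with 10 genes called the opposite way. RPKM-implied totals moved the median of all genes by -0.24 in MΔGΔT against MEF and -0.26 in MΔGΔT against MGT, and gave 2927 higher and 7159 lower genes in the first and 1869 higher and 7281 lower in the second, with 111 and 221 opposite calls. The shift follows from the totals themselves, and the counts do not show which totals are right. Without Gm26917 the counts were 4047 and 4086, 4797 and 4852, and 4078 and 3679.

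With each library left out in turn, 3863 to 4134 genes were higher and 3912 to 4141 lower in MGT than in MEF, 4657 to 4843 and 4729 to 4922 in MΔGΔT than in MEF, and 3894 to 4136 and 3456 to 3792 in MΔGΔT than in MGT. The lists called ranged from 18 to 19, 17 to 20 and 8 to 10. Equal replicate numbers are not said to pair libraries, and correlations of -0.18 to 0.12 between libraries of equal number, with 1 library closest to its own number, gave no sign that they do. With the replicate number as a block the counts were 4078 and 4001, 4794 and 4799, and 4005 and 3677, and camera also called skeletal muscle markers in MGT against MEF (adjusted p = 0.0468) and immediate early genes in MΔGΔT against MGT (adjusted p = 0.0277).

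An estimated correlation lowered the lists called from 19, 18 and 9 to 6, 5 and 5, and fry, which asks another question, called 27, 28 and 23. The correlation of the responses, 0.865, was 0.850 and 0.854 with the MEF libraries split, and 0.881 with at least 10 CPM in 5 libraries. The share of genes higher in MGT that lay higher still in MΔGΔT, 58.6%, was 59.1% in the MGT split, 58.2% with RLE and 63.5% at 2-fold, and reversed to 37.1% with library totals. For genes lower in MGT the share, 45.5%, was 46.7%, 44.7%, 38.9% and 29%. Apart from the effect of the totals, the cause was not tested.

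Of the values of named genes under the alternatives, 10989 stayed on their side of the threshold, 23 no longer passed and 17 newly passed. A further 5, called in the main or the alternative fit, changed sign. Changes of sign in values called in neither fit were not counted. These 5 were all in MΔGΔT against MGT. They were Mef2c with library totals (-0.0512, adjusted p = 0.231), and with RPKM-implied totals Mef2c (-0.13, adjusted p = 0.00758), Cox6a1 (-0.0318, adjusted p = 0.666), Cox8a (-0.00225, adjusted p = 0.977) and Sdhc (-0.0440, adjusted p = 0.528). Only Mef2c with RPKM-implied totals was called in the new direction. Gata4 came to 0.09 (adjusted p = 0.112) with RPKM-implied totals. Mrc1 lost its call in MΔGΔT against MGT without most single libraries. Mki67 in MGT against MEF passed with library totals (0.16, adjusted p = 0.0105) and without MEF replicate 1 (0.13, adjusted p = 0.0146), Lyz2 in MΔGΔT against MGT passed with limma-voom (0.40, adjusted p = 0.0105) and without MGT replicate 1 (0.48, adjusted p = 0.0402), and Foxa2 in MGT against MEF without MEF replicate 5 (3.48, adjusted p = 0.0203). Of the tests of lists, 1653 stayed the same, 40 lost and 47 gained a call, and 0 reversed. Alternatives written for normalized values (pseudocounts and filters) were not run, since counts were at hand. At this depth the smallest simulated change was recovered for 60% to 70% of the genes drawn, which left out genes of low level, so small changes can be missed. Far fewer genes were changed in the simulations than are called in the real comparisons, so these shares need not hold for the real data. Genes with 0 to 3 counts in a group have only bounds or wide intervals.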

Other observations

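None of the tests in this part was chosen only after the result was seen. The RPKM-implied totals named with some medians were.

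Markers of other cell types showed a few large changes of single genes, and of these lists the neural one mostly fell against MEF. Of 12 endothelial markers, 5 rose and 5 fell in MGT against MEF (median 0.07, mean -0.32, adjusted p = 0.881). In MΔGΔT against MEF they were 5 and 5 (median 0.18 but -0.05 with RPKM-implied totals, mean -0.28, adjusted p = 0.813), and in MΔGΔT against MGT 6 and 5 (median 0.05 but -0.01, -0.125 and -0.21 with upper-quartile factors, library totals and RPKM-implied totals, adjusted p = 0.762). The VEGF receptor gene Flt1 rose in MΔGΔT from 117 ± 7.50 to 486 ± 18.8 CPM (SD, n = 5), a log2 fold change of 2.05 ± 0.0443 (SE), and Vwf, which endothelium stores, fell by 3.35 in MGT and by 3.61 in MΔGΔT. Of 8 epithelial and mesothelial markers, 4 rose and 4 fell in MGT (median 0.12, mean -0.33, adjusted p = 0.881), and 4 and 3 in MΔGΔT (median 0.62, adjusted p = 0.472). Between the transduced groups 3 rose and 3 fell (median -0.07, mean 0.48, adjusted p = 0.5). The mesothelial surface gene Msln went from 4.77 ± 0.725 CPM in MEF to 18.3 ± 2.90 in MGT and 87.1 ± 7.03 in MΔGΔT, while Lrrn4 fell by 4.05 and 5.31. Neural markers had 6 down and 1 up of 9 in MGT (median -1.04, adjusted p = 0.0684, but 0.0395 with library totals), 7 and 1 in MΔGΔT (median -1.64, adjusted p = 0.0558, but 0.0486 without MEF replicate 3), and 3 and 2 between these groups (median -0.26, adjusted p = 0.762, but 4 and 1 with library totals and 5 and 1 with RPKM-implied totals). Gfap, a glial filament gene, fell by 3.45 in MGT, but Nes, an intermediate filament of precursor cells, rose by 2.68 ± 0.0449 in MGT and by 4.48 ± 0.0452 in MΔGΔT.

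Of 15 cartilage and bone markers, 6 rose and 6 fell in MGT against MEF (median 0.02 but -0.009 with upper-quartile factors, adjusted p = 0.633), and 8 and 5 in MΔGΔT against MEF (median 0.38, adjusted p = 0.347, and 7 and 7 with RPKM-implied totals). Between the transduced groups 6 rose and 4 fell (median 0.02 but -0.04, -0.16 and -0.24 with upper-quartile factors, library totals and RPKM-implied totals, adjusted p = 0.525). The cartilage proteoglycan gene Acan went from 0.173 ± 0.116 CPM in MEF to 8.43 ± 0.398 in MGT and 56.9 ± 4.80 in MΔGΔT, and the cartilage regulator Sox5 rose by 3.65 ± 0.0959 in MGT. Only 4 endoderm and liver markers were tested, and Gata4, a factor, is 1 of them. In MGT 2 rose and 1 fell, or 3 and 1 adjusted over the list alone, and in both MΔGΔT comparisons 3 rose and 1 fell. Foxa2, a pioneer factor of endoderm (chromosome 2, 148042877 to 148046969), had 365 counts in MΔGΔT against 1 in MEF (ratio 356, interval 63.5 to 14100), and 7 counts in MGT (adjusted p = 0.0753 against MEF). Adipocyte markers had 2 up and 2 down of 8 between the transduced groups (median -0.05, adjusted p = 0.762), but 1 up and 4 down with library totals (median -0.225) and 0 and 4 with RPKM-implied totals (median -0.31). Corepressors and partners of MEF2 and GATA had 11 up and 2 down of 17 in MGT against MEF (median 0.11, adjusted p = 0.0906). In MΔGΔT they had 8 up and 4 down against MEF (median 0.008, adjusted p = 0.475, but 5 up and 8 down with library totals and 4 and 9 with RPKM-implied totals) and 4 up and 6 down against MGT (median -0.02, adjusted p = 0.5). With library totals the latter were 2 up and 13 down (median -0.19), and with RPKM-implied totals 1 and 14 (median -0.28). Hdac9, a repressor of MEF2 factors, rose by 1.36 ± 0.0926 in MΔGΔT against MEF and by 0.85 ± 0.0841 against MGT. Of 12 mitochondrially encoded genes, 0 rose and 1 fell in MGT against MEF, with 0 adjusted over the list alone (median -0.12, adjusted p = 0.439), and 6 rose and 0 fell in MΔGΔT against MEF, or 5 and 0 adjusted over the list alone (median 0.46, adjusted p = 0.14). With library totals the latter were 5 and 1 (median 0.36), and with RPKM-implied totals 2 and 1 (median 0.22).

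The 10 most abundant genes took 11 ± 0.425% of the counts in MEF, 8.46 ± 0.253% in MGT and 9.41 ± 0.153% in MΔGΔT. The predicted gene Gm26917 took 1.59 ± 0.198%, 1.80 ± 0.189% and 1.59 ± 0.113%.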
